A study of Homo sapiens with 61 samples.

How the data were processed

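RNA was taken from 61 HAP1 cultures at 70 to 80% confluence, 60 of them CRISPR knockouts of 1 gene each and 1 wild type. Per the labels, media held 10% fetal bovine serum, RNA was isolated with RNeasy columns, and poly(A) libraries were made with a directional kit. The deposited values are counts of reads per gene, made by the authors with STAR 2.7.9a against hg38 per the submitters' processing notes. The release of the gene annotation was not given in the sources used here. Each file of counts gives unstranded, forward and reverse columns. The forward column held 6.49% to 7.02% of the strand-assigned reads, as a reverse-stranded kit gives, so the reverse column was used. It equalled the authors' merged table of counts in all 2328004 values compared. The merged table has 17 columns that belong to no sample used here, and these were left out.

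The gene tables held 60609 entries. Of these, 45 copies of pseudoautosomal genes on the Y chromosome with 4 reads in all were left out. Names and positions were joined from GENCODE 29 on GRCh38, which gave a position for 96.5% and a name for 99.6% of genes. Reads that name no gene stayed out of library sizes and tests. Unmapped reads were 3.69% to 6.34%, multimapping reads 2.15% to 5.62%, reads in no feature 2.56% to 4.45% and ambiguous reads 4.76% to 5.22% of the reads of a library. Library totals ran from 21,408,443 to 38,168,852.

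Genes with a mean count of at least 10 over the 61 libraries were kept, which left 16502. Counts were scaled by TMM and tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, and p-values were adjusted over genes by Benjamini-Hochberg. The medium comparison (30 rich minus 30 minimal knockout libraries) and the respiration comparison (7 knockouts minus 53, with medium as a covariate) called genes at an adjusted p under 0.05. Each knockout and the wild type were tested as 1 library against the other 60, with medium as a covariate, and called at an adjusted p under 0.05 and a change of at least 2-fold. That test takes the spread of a single library to be that of the others. CPM are counts divided by the TMM-scaled library size, and log2 CPM used a prior count of 2. For profiles, lists and chromosomes log2 CPM were centred on the mean of each medium.

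Other tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. The number of targets that were lowest in their own library was set against 100000 permutations of targets over libraries within medium. Lists of genes were compared between media, and between respiration and other knockouts, by permutation of library labels with 100000 resamples. A list matched to a knockout was ranked by its absolute mean deviation among the 61 libraries, without the knocked-out gene, and the exact p is that rank over 61. The 9 preset pairs were tested by the mean Pearson correlation across genes with 100000 permutations of library labels within medium. Chromatin knockouts in minimal medium were compared by an exact permutation test over 593775 splits. Chromosome shifts of at least 0.4 over at least 100 genes, and neighbours of a target within 500 kb at a log2 fold change of -3 or lower, were listed without a test.

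The tests, the thresholds, the 25 gene lists, the pairs, the knockout classes and the rule for named genes were fixed before the data were examined. The rule took, among called protein-coding genes with a mean of at least 5 CPM, the 10 largest rises and 10 largest falls of the medium and respiration comparisons, and called members of the lists. For knockouts it took the target, up to 6 called members of a matched list, and the 3 largest rises and falls with a mean of at least 5 CPM or at least 20 CPM in the knockout. This was done for knockouts with a matched list, for the 5 knockouts with most calls and for the wild type. Adjustment over a list alone means Benjamini-Hochberg over the members of that list. The 5 libraries with a shared profile were found after the data were examined, as the only set of 3 or more libraries linked by correlations of at least 0.6. The analyses without them, the segments of chromosomes, the absent genes, the lists with each respiration knockout left out and the fit without the 5 and GSK3B were added then.

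Alternatives were DESeq2 1.42.0, no low-count filter, mean counts of at least 50 or 100, unstranded counts, library totals without TMM, blocks of library numbers (1 to 20, 21 to 40, 41 to 60 and 61 to 82), libraries 1 to 20 alone, the wild type added, subsets of knockouts, 1 medium alone, medians and unit-SD scaling for lists, and Spearman correlation. The labels do not say that library numbers are batches. The blocks held 7 minimal and 8 rich knockouts, then 14 and 1, then 6 and 12, and last 3 and 9.

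The pipeline was tested on simulated data with 200 changed genes. The medium test found 90% of 2-fold and 98% of 4-fold changes and called 5 of 16302 unchanged genes. The respiration test found 80% and 95% and called 11, and the single-library test found 16% and 68% and called 4. The simulated libraries were drawn independently, without the shared profile or the chromosome shifts of the real ones. These rates therefore need not hold for the real libraries. A count of 0 in 1 library allows up to 3 counts (95% upper limit), from which the smallest fold difference was taken, and for 1 to 3 counts the ratio is given with its 95% interval. Intervals and limits cover counting error only, since the reads have no molecular identifiers.

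The 25 lists covered targets of hypoxia-inducible factors, NRF2, YAP and TEAD, ATF4, MAP kinases, WNT, SRF and p53. They also covered sterol and fatty acid synthesis, lysosomal genes, the ER unfolded protein response, the proteasome, tubulins, mitochondrial transcripts, nuclear respiratory genes, mitochondrial stress, selenoproteins, glycolysis, serine and one-carbon genes and the cell cycle. Markers of blood cells, fibroblasts and epithelia, and nuclear RNAs as a sign of RNA quality, made up the rest. None of the 25 passed between media or in the respiration comparison, and none of the 22 matched pairs passed, each after adjustment.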

Results

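Poly(A) RNA was sequenced from 61 cultures of HAP1, a near-haploid human cell line widely used for gene editing because 1 cut can remove the only copy of a gene. In 60 cultures the label named 1 gene knocked out with CRISPR, and 1 culture was wild type. Per the labels, 30 knockouts grew in a minimal medium, DMEM with 10 mM glucose and 1 mM glutamine. The other 30 and the wild type grew in a rich medium, IMDM with 25 mM glucose and 1 mM pyruvate, so the base media differed too. Each knockout had 1 library, so no knockout was replicated, and each value for a knockout below comes from 1 library. The libraries held 21,408,443 to 38,168,852 assigned reads, with a median of 30,572,059. The mean was 30,472,579 ± 4,005,891 in minimal medium and 31,014,245 ± 2,642,258 in rich medium (SD, n = 30 each). The wild type held 30,778,685 reads. Between 22,364 and 24,478 genes had at least 1 read, and 16502 genes were tested. Positions are GRCh38.

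The first comparison asked whether the transcript of the gene named in each label was low in that library. CDC42, a small GTPase that sets cell polarity (ENSG00000070831, chromosome 1: 22052627–22092946), showed the largest loss. It stood at 13.2 CPM (reads scaled to library size) in its own library against 306.04 ± 42.6 in the other minimal-medium libraries (SD, n = 29), a log2 fold change of -4.53 (SE 0.26, adjusted p = 3.61e-21). TUBB, a beta-tubulin, fell from 2473 to 233 CPM, a log2 fold change of -3.41. The apoptosis genes PDCD5 and BAX fell by 3.29 and 2.81. The mitochondrial enzymes PC, which makes oxaloacetate from pyruvate, and COQ7, which acts late in coenzyme Q synthesis, fell by 2.68 and 2.67. The transcripts of FASN, which builds fatty acids, KAT7, a histone acetyltransferase, and RHOA, a small GTPase of the actin cytoskeleton, had values of -1.72, -1.70 and -1.37 and were called lower as well.

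Of 58 knockouts with 1 measured target, 36 had the lowest value of that gene among all 61 libraries. Permuted labels gave a mean of 1.65 and at most 10 (permutation p = 1e-05, the smallest that 100000 permutations allow). The transcript lay below the mean of its medium in 51 knockouts, and 26 of the 58 passed both thresholds for a fall. The median log2 fold change was -0.94. Small insertions or deletions need not lower a transcript, so a normal level does not by itself contradict a label. In 7 libraries the target was not below the mean, and in 2 of these it rose. KEAP1, which targets the antioxidant regulator NRF2 for degradation, was at 228 CPM against 128 in the library labelled KEAP1, a log2 fold change of 0.83 (adjusted p = 0.00580). SIN3A, the scaffold of a histone deacetylase complex, was at 376 CPM against 198 in the library labelled SIN3A, with 0.92 (adjusted p = 0.00616). The other 5 had values of 0.60 for TAF5L, 0.37 for BRD4, 0.25 for PSMC5, 0.16 for TMEM126A and 0.05 for PIGO. SLX1 has near-identical copies with mean counts of 0.03 and 1.64 and could not be measured. The label TAZ names 2 possible genes, TAFAZZIN (-0.18) and WWTR1 (-0.61), and neither was called.

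**Figure D1:**
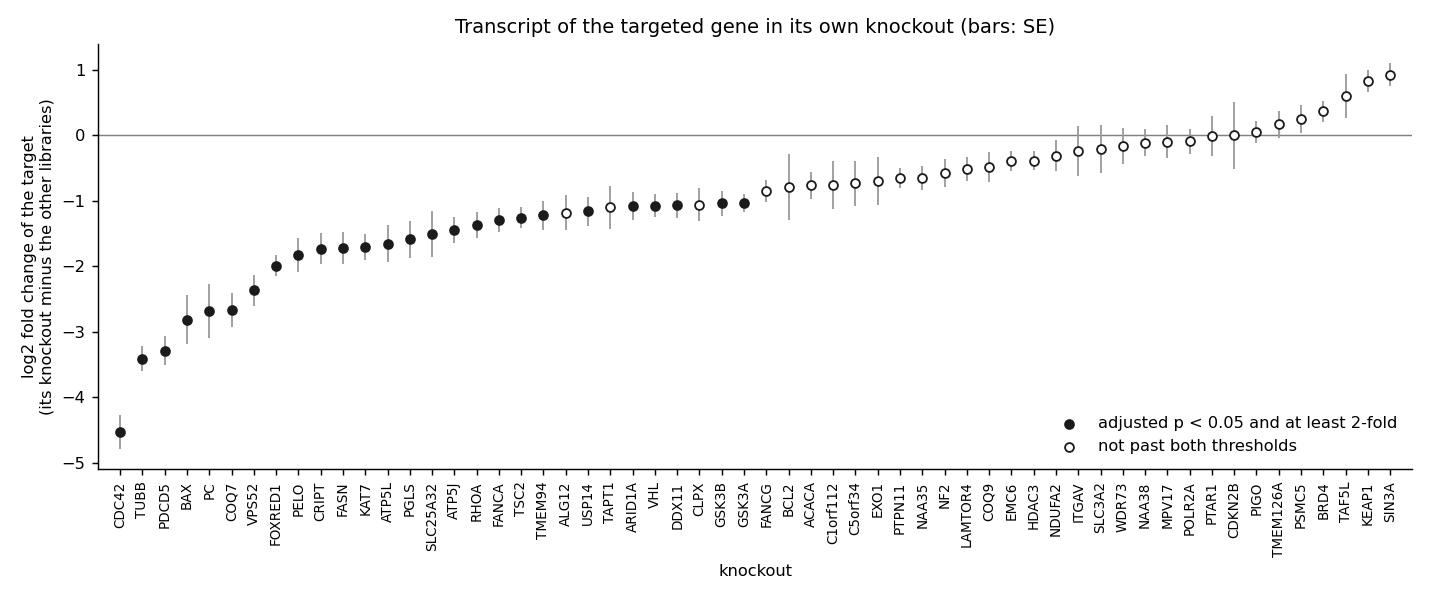
Log2 fold change of each knockout's own target gene in its 1 library against the other libraries, with the standard error of the fit. Filled points passed both thresholds, an adjusted p under 0.05 and a change of at least 2-fold.

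A set of 5 rich-medium libraries, labelled C5orf34, CRIPT, MPV17, POLR2A and TMEM126A, shared an expression profile that no other library had. Their profiles correlated with each other at 0.630 to 0.860, with a median of 0.785, and with any other knockout at 0.207 at most. All 5 expressed genes that were near silent elsewhere. MEIOB, a meiotic recombination gene, stood at 78.2 to 129 CPM in the 5 and at 0.512 CPM or less in the other 55 knockouts. The zinc finger genes ZNF793, ZNF208, ZNF90 and ZNF43, with KIAA1210 and LINC01602, were on in the same way, and LONRF3 was at 26.1 CPM or more in the 5 and at 4.92 CPM or less in the other knockouts. FXYD6, a regulator of the sodium pump, had 0 counts in all 5 and a median of 56.1 CPM in the other knockouts. TP53I11 stood at 0.0337 CPM or less in the 5 and at 20.7 CPM or more elsewhere, and 13 genes had at most 3 counts in all 5 and in no other library. Fibroblast markers were low in all 5, with list means of -1.78 to -1.01 (SD 1.11 over the other libraries). The nuclear RNAs listed as a sign of RNA quality were at 0.37 to 0.78 in 4 of the 5 and at -0.18 in CRIPT (SD 0.25). These 5 were found in the data, so the set was not tested as a group. The main counts below are given with and without them.

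The labels give the growth medium of every library, and the comparison of media asked which genes differed between knockouts grown in rich and in minimal medium. Each knockout grew in 1 medium only, so this comparison is also one between 2 sets of knockouts. Of 7 respiration knockouts 6 grew in rich medium, and of 7 chromatin and transcription knockouts 6 grew in minimal medium. EGR1, an immediate-early transcription factor that responds to growth factors, was lower in rich medium, with 11.5 ± 16.2 CPM against 44.8 ± 62.3 (SD, n = 30 each). Its log2 fold change was -1.97 (SE 0.43, adjusted p = 0.0022). KLF2, a transcription factor that responds to blood flow and statins, was lower by a log2 fold change of -1.34 (SE 0.27, adjusted p = 0.000939), with 5.43 ± 2.69 CPM against 13.7 ± 22.3. The RHOA library alone held 122.9 CPM of KLF2. GDF15, a stress-induced hormone (-1.49), HES1, a NOTCH target (-1.27), LIF, a cytokine (-1.14), EPHA3, an ephrin receptor (-0.96), SERTAD1 (-0.66), PIM1, a survival kinase (-0.53), APLN (-0.51) and KLF6 (-0.49) completed the 10 largest falls. Without the 5 libraries all 209 falls kept their sign, but of these 10 only EGR1 and KLF2 stayed called. HES1 (-1.24), LIF (-0.94), EPHA3 (-0.86), SERTAD1 (-0.67), PIM1 (-0.47) and KLF6 (-0.44) kept most of their fold. Their edgeR adjusted p were 0.140, 0.168, 0.179, 0.136, 0.142 and 0.114 in that order, while APLN went to -0.34 (adjusted p = 0.199). In libraries 1 to 20 alone HES1 turned to 1.52 and SERTAD1 to 0.018, neither called.

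Many of the largest rises in rich medium were highest in the 5 libraries. KIAA1210 (8.34), MEIOB (7.97), AMBN, which encodes an enamel protein (7.81), ZNF793 (6.73), IFI16, a DNA sensor (6.68), ESX1 (5.84), ACTL8 (5.47), ALDH1A2, a retinoic acid synthesis enzyme (3.68), KLF4, a pluripotency factor (3.15), and TEX19 (3.11) had the largest rises. ACTL8 was at 594 to 679 CPM in the 5 and at 5.12 CPM or less in the other knockouts. Without the 5, ACTL8 had a log2 fold change of -0.23, KIAA1210 of -0.15 and TEX19 of -0.32, so their direction turned, and AMBN (0.54), ESX1 (0.13), ZNF793 (0.13) and MEIOB (0.17) were not called. IFI16 and ALDH1A2 stayed called, at 4.33 (adjusted p = 0.00423) and 3.002 (adjusted p = 0.0194). The GSK3B library alone held 52.9 CPM of IFI16, and without it as well the value was 3.12 (adjusted p = 0.0359). Of all 742 rises 692 kept their sign without the 5, and 40.7% of the rises of at least 2-fold stayed at least 2-fold.

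Without the 5 libraries IFI16 averaged 1.77 CPM and fell below the 5 CPM of the naming rule. Among genes with at least 5 CPM, ALDH1A2 (3.002), HPGD, which breaks down prostaglandins (1.502), LAMA4, a laminin (0.94), KLHL24 (0.58), SLC5A3, an inositol transporter (0.55), SNX16 (0.51), GPR137B, a lysosomal membrane protein (0.50), AKT3, a growth factor kinase (0.50), ZNF250 (0.49) and PAPLN (0.48) were the largest rises. AKT3 stood at 70.9 ± 20.3 CPM (SD, n = 25) against 50.01 ± 13.7 (n = 30; adjusted p = 0.00973). EGR1 (-1.76, adjusted p = 0.043) and KLF2 (-1.26, adjusted p = 0.0264) were still called lower, followed by IER5 (-0.63), MYCBP (-0.39), PUDP (-0.29) and MED10 (-0.25). GDF15 (-1.40, adjusted p = 0.151) and KLF4 (1.66, adjusted p = 0.0609) were no longer called.

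Some members of the preset lists changed with the medium. TPP1, a lysosomal peptidase, rose from 36.2 ± 6.19 to 44.7 ± 10.1 CPM (log2 fold change 0.30, SE 0.07, adjusted p = 0.00753). FNIP1 (0.38) and FNIP2 (0.41), which act with folliculin in nutrient sensing at the lysosome, rose too, and FNIP2 lost its call without the 5 at much the same fold (0.38, adjusted p = 0.0591). The proteasome subunits PSMB2 (-0.14), PSMD13 (-0.16) and PSMD7 (-0.12) were called lower by small amounts, PSMD13 without the 5 as well (adjusted p = 0.0331), while PSMB2 and PSMD7 kept their folds (-0.14 and -0.12) but not their calls. The mitochondrially encoded complex I transcripts MT-ND1 (-0.33), MT-ND2 (-0.34) and MT-ND3 (-0.45) were called lower with all libraries. Without the 5 their folds were as large (-0.33, -0.40 and -0.43), with adjusted p of 0.134, 0.0612 and 0.124. The nuclear genes SDHC (0.26) and NDUFV1 (0.16) of the respiratory chain were called higher, and without the 5 they were not (0.08 and 0.11, adjusted p = 0.252 and 0.168). OIP5-AS1, a long non-coding RNA that the preset list of nuclear RNAs held as a sign of RNA quality, rose from 136 ± 21.3 to 170 ± 29.2 CPM (0.31, adjusted p = 0.000718; without the 5, 0.27 and adjusted p = 0.0254).

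As groups, 0 of the 25 lists passed (permutation test of library means, Benjamini-Hochberg adjusted), and 5 had an unadjusted p under 0.05. The YAP and TEAD targets, which respond to cell density and stiffness, had a list mean of -0.22 ± 0.56 in rich medium and 0.20 ± 0.57 in minimal medium (SD, n = 30 each; p = 0.00524, adjusted p = 0.0921). For targets of p53 the difference was -0.47 (p = 0.00737, adjusted p = 0.0921), and 5 members fell when adjusted over the list alone. The proteasome list differed by -0.09 (p = 0.0197, adjusted p = 0.125), with 13 members lower when adjusted over the list alone. Fibroblast markers differed by -0.73 (p = 0.0199, adjusted p = 0.125) and WNT targets by 0.17 (p = 0.0392, adjusted p = 0.196). Targets of MAP kinase signalling, which include EGR1, differed by -0.30 (p = 0.0554, adjusted p = 0.231). For the other lists, glycolysis and sterol synthesis among them, adjusted p ran from 0.385 to 0.954. Without the 5 libraries fibroblast markers differed by -0.44 (p = 0.156) and WNT targets by 0.13 (p = 0.114). YAP and TEAD targets (-0.33, p = 0.0348), p53 targets (-0.39, p = 0.0311), the proteasome (-0.10, p = 0.0147), lysosomal genes (0.10, p = 0.0381) and MAP kinase targets (-0.37, p = 0.0311) had an unadjusted p under 0.05, and the smallest adjusted p was 0.190.

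In total edgeR called 951 genes between media, 742 higher and 209 lower in rich medium, and 299 of them changed at least 2-fold. These p-values measure the spread between libraries of different knockouts, not between repeats of 1 culture. Without the 5 correlated libraries 94 genes were called, 73 higher and 21 lower, and 84 of these were among the 951 with the same direction. Leaving out 5 other rich-medium libraries instead gave 673 to 1550 calls in 20 draws. Those draws kept the 5 correlated libraries, which then weighed more among the rich-medium libraries, so they are no neutral baseline. Library numbers overlap with medium, and with library-number blocks 421 genes were called. Among libraries numbered 1 to 20, where 7 minimal and 8 rich libraries stood side by side, edgeR called 0 genes, with 1155 at an unadjusted p under 0.05.

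**Figure D2:**
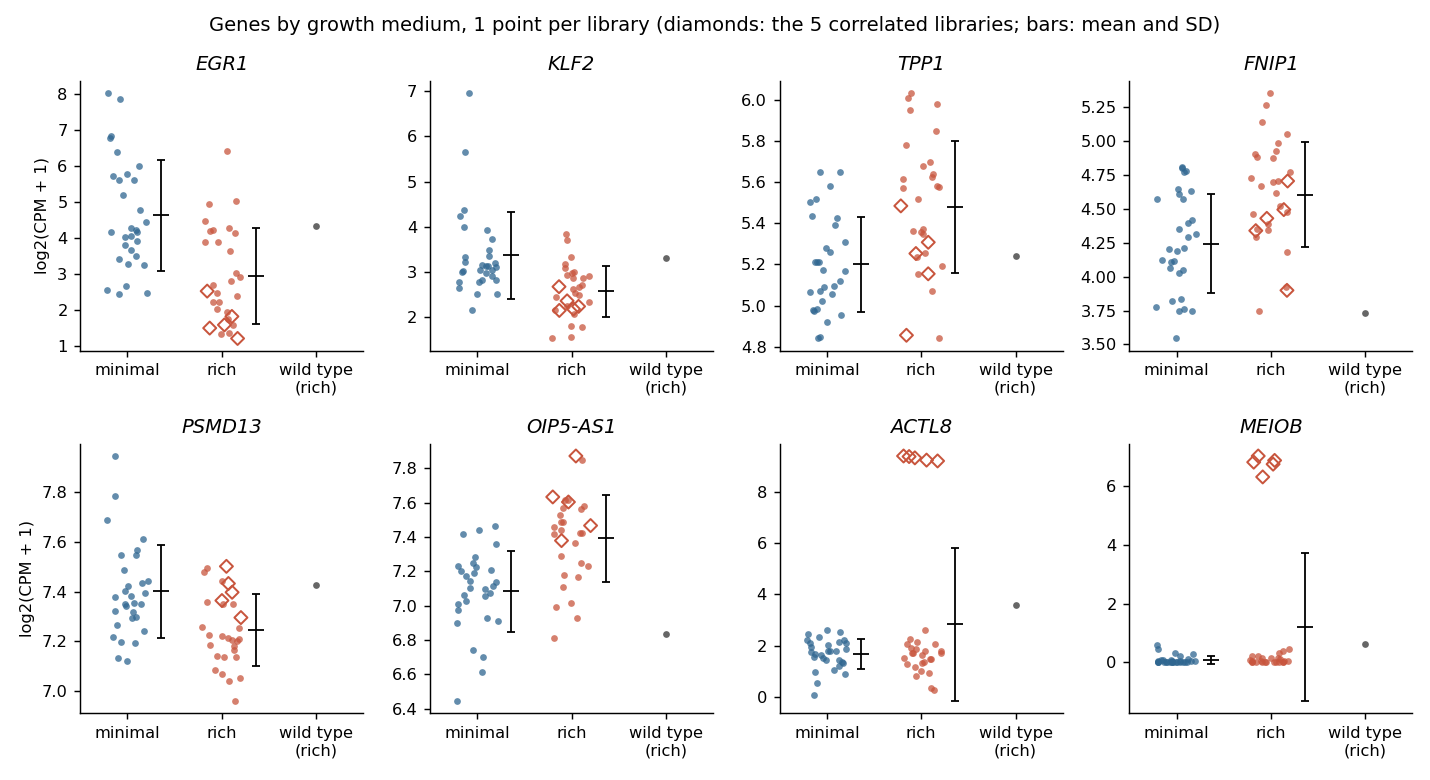
Expression of 8 genes in each knockout library by medium, as log2 of CPM plus 1, with the mean and SD of those values (n = 30 each). Diamonds mark the 5 libraries with the shared profile.

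The respiration comparison asked whether loss of the respiratory chain, ATP synthase or coenzyme Q synthesis gave a common response. It set 7 knockouts (ATP5J, ATP5L, COQ7, COQ9, FOXRED1, NDUFA2 and TMEM126A) against the other 53. PCK2, the mitochondrial enzyme that feeds gluconeogenesis and a target of the stress factor ATF4 (ENSG00000100889, chromosome 14: 24094053–24110598), came closest to a call. Its log2 fold change was 1.26 (SE 0.25, adjusted p = 0.073). It stood at 393 CPM in the NDUFA2 library, the highest of all, and at 260 in ATP5L and 166 in ATP5J, but at 72.4 in the library labelled TMEM126A and 62.1 in COQ7. PCK2 was called by DESeq2 (1.25, adjusted p = 0.00628), in rich medium alone (1.45, adjusted p = 0.0271), without the count filter (adjusted p = 0.0395) and without COQ7 (adjusted p = 0.00646) or TMEM126A (adjusted p = 0.0181). Without NDUFA2 the value of PCK2 by respiration class was 0.91 (adjusted p = 0.977), and with library-number blocks at 1.22 (adjusted p = 0.272). Without the 5 correlated libraries PCK2 was called at 1.38 (adjusted p = 0.0192), together with DEPP1, a FOXO target, at 2.90 (adjusted p = 0.0230). DEPP1 rested on the NDUFA2 library, which held 70.4 CPM, and with all libraries but that one its value was -0.15.

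The list of ATF4 stress targets, which covers amino acid synthesis and tRNA charging, was 0.33 higher in the 7 knockouts (permutation p = 0.0288, adjusted p = 0.495). When adjusted over the list alone, 11 of its members were higher. Serine and one-carbon genes were 0.15 higher (permutation p = 0.0396, adjusted p = 0.495), with 3 members higher when adjusted over the list alone. Both rested largely on the NDUFA2 library (1.44 for ATF4 targets, 0.48 for serine genes), followed by ATP5L (0.70 and 0.40), and COQ7 (-0.21 and -0.15) and TMEM126A (-0.17 and -0.12) were below 0. Without NDUFA2 the differences were 0.13 (permutation p = 0.322) and 0.09 (permutation p = 0.194), chosen after the values were seen. Without the 5 libraries the adjusted p of both lists was 0.204. The other 23 lists had adjusted p of 0.827 or more.

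No gene passed in this comparison. The count was 0 by edgeR, with 1279 genes at an unadjusted p under 0.05, and 4 by DESeq2. In the rich medium alone, where 6 of the 7 grew, 3 genes were called. Leaving out the library labelled TMEM126A gave 15 calls and leaving out COQ7 gave 4, while leaving out any other of the 7 gave 0.

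The test of single knockouts asked which genes in 1 library differed from the mean of the other 60, with medium as a covariate. HDAC3 is the catalytic subunit of the NCoR corepressor complex. In its library EDIL3, an integrin ligand, FOXH1, a SMAD partner, and PRSS8, a membrane protease, were higher by log2 fold changes of 7.52, 6.21 and 5.96. The transcription factors BCL11A and FOXA1 were lower, at -3.41 and -3.18, and so was SMAP1 at -2.79. The NDUFA2 library, labelled for a subunit of complex I whose transcript stood at 80.6% of the others (log2 fold change -0.31, adjusted p = 0.495), had higher DEPP1 (4.87), NUPR1, a stress-induced chromatin protein (3.87), and SPOCK2, a matrix proteoglycan (5.00). FBXL7 had 0 counts there and was at least 184-fold lower, counting error only. ETV1, a MAP kinase target, had 1 count against 6.58 CPM elsewhere, a ratio of 180 (95% interval 32.3 to 7103). CEBPZOS was lower by a log2 fold change of -7.31. Outside this library FBXL7 had at most 3 counts in COQ9 too, and CEBPZOS in FANCA.

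The SLX1 library, labelled for a structure-specific nuclease, had higher RTP1 (7.496), MEST, an imprinted gene (5.80), and COL14A1, a collagen (5.57). GTSF1, which acts in the piRNA pathway, had 0 counts there and was at least 793-fold lower. MTARC1 was at least 170-fold and DDIT4L at least 90.1-fold lower. Neither loss was particular to SLX1. MTARC1 had at most 3 counts in CDKN2B as well, and DDIT4L in ATP5L, CDKN2B, PGLS and PTPN11. In the POLR2A library ZCCHC12 (5.19), IER3 (3.48) and the linker histone H1-2 (3.27) were higher, and FXYD6, TP53I11 and CSRP1 had 0 counts, at least 549-, 429- and 415-fold lower. The library labelled TMEM126A had higher KCNK9, a potassium channel (5.02), LONRF3 (3.50) and JCAD (2.61), and 0 counts of FXYD6, RIMS4 and TP53I11, at least 567-, 459- and 443-fold lower. FXYD6, TP53I11, CSRP1 and LONRF3 belong to the profile that these libraries shared with 3 others. RIMS4 had at most 3 counts in C5orf34 and POLR2A too.

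Across the 60 knockouts edgeR made 3140 calls, 1117 higher and 2023 lower, with a median of 5 per knockout. The library labelled TMEM126A had the most (511), before NDUFA2 (467), POLR2A (403), HDAC3 (372) and SLX1 (69 higher and 168 lower), and these 5 held 63.4% of all calls. C5orf34 (229), the library labelled BRD4 (214), CRIPT (135) and KAT7 (117) followed. BCL2, CLPX, EMC6, ITGAV, NAA35, PTAR1, PTPN11 and TAF5L had none. Of the 168 lower calls in SLX1, 74 lay on chromosome 13 and 56 on the X chromosome. Both chromosomes were low as a whole in that library, so its count is not one of genes spread over the genome. Counts in the 5 correlated libraries depended on which libraries they were set against. Against libraries outside the 5 the total rose, mostly through calls in the 5 themselves. Within rich medium alone TMEM126A had 3 calls, MPV17 3, C5orf34 10 and POLR2A 41, and against libraries outside the 5 TMEM126A had 1645 and POLR2A 1441. The test assumes that a single library varies as the others do, which nothing here could check. In simulated libraries it found 16% of 2-fold and 68% of 4-fold changes.

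**Figure D3:**
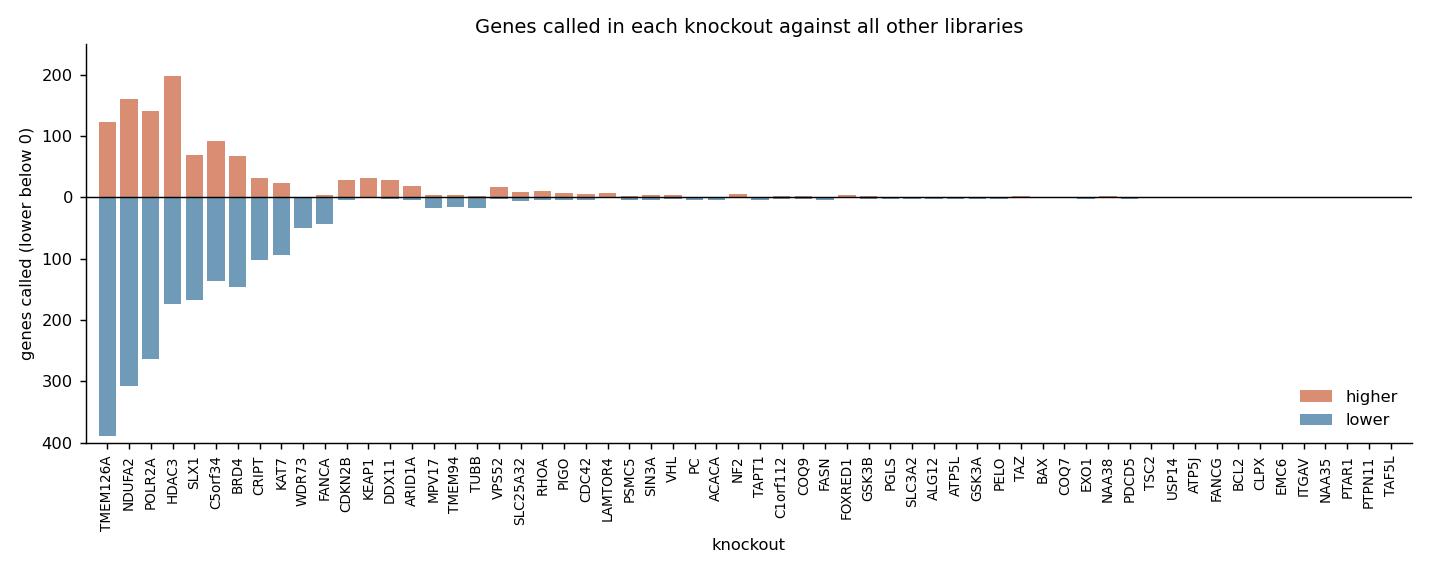
Number of genes called higher and lower in each knockout library against the other 60 libraries. Each bar is 1 library.

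Among minimal-medium libraries, those labelled for chromatin and transcription genes had a higher median number of called genes than the rest. HDAC3, with 372, the library labelled BRD4, a reader of acetylated histones, with 214, and KAT7, with 117, led this class. ARID1A had 22, SIN3A 7 and TAF5L 0. Of the 117 in KAT7, 31 were lower genes in a chromosome 10 segment with a median of -0.61. In 3 of the 6, labelled SIN3A, TAF5L and BRD4, the target transcript was not low. The medians were 69.5 in the 6 libraries labelled for chromatin genes and 3.5 in the other 24, a difference of 66 (exact permutation p = 0.00139). Without BRD4 the difference was 18.5 (exact permutation p = 0.0203).

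For 22 pairs of a knockout and a pathway, the preset list asked whether the pathway moved in its own knockout. In the library labelled KEAP1 the NRF2 antioxidant genes were raised, although the KEAP1 transcript itself was not low there. AKR1C2 (ENSG00000151632, chromosome 10: 4987400–5018031), a steroid and aldehyde reductase, stood at 577 CPM against 0.380 in the other minimal-medium libraries (log2 fold change 10.59, SE 1.40). AKR1C1 (7.98), AKR1C3 (7.11), GPX2, a glutathione peroxidase (5.29), OSGIN1 (4.42) and TXNRD1, a thioredoxin reductase (2.18), rose with it. CES1, a drug-processing esterase outside the list, rose by 10.90. The list mean was 2.498 above the others, whose SD was 0.43, with 22 of 23 members higher and 11 called. With the median over genes in place of the mean the value was 1.26, the second highest (exact p = 0.0328). By DESeq2 the folds were similar, but the adjusted p were 0.0586 for AKR1C2 in KEAP1, 0.131 for CES1 in KEAP1 and 0.763 for GPX2 in KEAP1. Fibroblast markers were at -2.32 in this library, the lowest of all.

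In the ALG12 library, labelled for a mannosyltransferase that builds N-glycans, all 20 genes of the unfolded protein response of the endoplasmic reticulum (ER) were above the mean of the medium. The list mean was 0.59 against an SD of 0.14 in the other libraries. CALR, a chaperone of newly made glycoproteins, rose to 2179 CPM against 1076 ± 184 (SD, n = 29; adjusted p = 0.0369), and 10 members rose when adjusted over the list alone. In the NF2 library, labelled for an upstream activator of the Hippo pathway, the YAP and TEAD list was at 1.20, the second highest, with 17 of 20 members higher and 0 called (exact p = 0.0328). Outside the list the NF2 library had higher RAB34 (4.12), VGLL3, a partner of TEAD factors (3.25), and UACA (1.98). Fibroblast markers were at 1.87 and blood-cell markers at 1.23 in this library, each at rank 3 of 61.

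The 2 knockouts of fatty acid synthesis had higher list means for that pathway, 0.28 for FASN (14 of 15 members higher) and 0.31 for ACACA (10 of 15 higher), each with exact p = 0.0492. With the median over genes these p were 0.0656 and 0.115. TSC2, a brake on mTORC1, had 23 of 27 lysosomal genes higher, with a mean of 0.32 (exact p = 0.0492, and 0.148 with the median over genes). RHOA had the lowest mean for SRF and actin genes, -0.69 (exact p = 0.0820), and PTPN11, a phosphatase that promotes MAP kinase signalling, the second lowest for MAP kinase targets, -0.91 (exact p = 0.115). In FANCA and FANCG, DNA crosslink repair knockouts, all 21 measured p53 targets were above the mean, at 1.02 (exact p = 0.0984) and 0.86 (exact p = 0.164). The wild type was at 0.80 for this list, whose SD over all libraries was 0.64. These values therefore did not set FANCA and FANCG apart from the wild type. The TUBB library had a mean of 0.33 for the other tubulins (exact p = 0.0820), with 4 higher when adjusted over the list alone. With the median over genes it ranked first (0.42, exact p = 0.0164), and with genes scaled to unit SD the exact p was 0.0328. Blood-cell markers were at 1.38 in this library, the highest of all.

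Other matched pathways showed values near the rest. VHL, which marks hypoxia-inducible factors for degradation, gave 0.21 for hypoxia targets (exact p = 0.180), with 13 of 24 members higher. GSK3B gave 0.20 for WNT targets (exact p = 0.590), the library labelled PSMC5 0.14 for the proteasome (exact p = 0.311) and VPS52 -0.15 for sterol synthesis (exact p = 0.541). SLC3A2 gave -0.21 for ATF4 targets (exact p = 0.492). CLPX (0.09) for ATF4 targets, EMC6 (0.03) for the ER list, LAMTOR4 (-0.02) for lysosomal genes, CDC42 (-0.07) for actin genes, DDX11 (-0.10) for p53 targets and MPV17 (0.06) for mitochondrial transcripts were closer to 0.

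With 61 libraries the smallest possible exact p is 0.0164, reached by KEAP1 and ALG12. Of the 22 pairs 0 passed after adjustment, the smallest adjusted p was 0.180, and 6 had an exact p under 0.05. Rank 1 was reached by 2 pairs where 0.361 would be expected by chance.

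**Figure D4:**
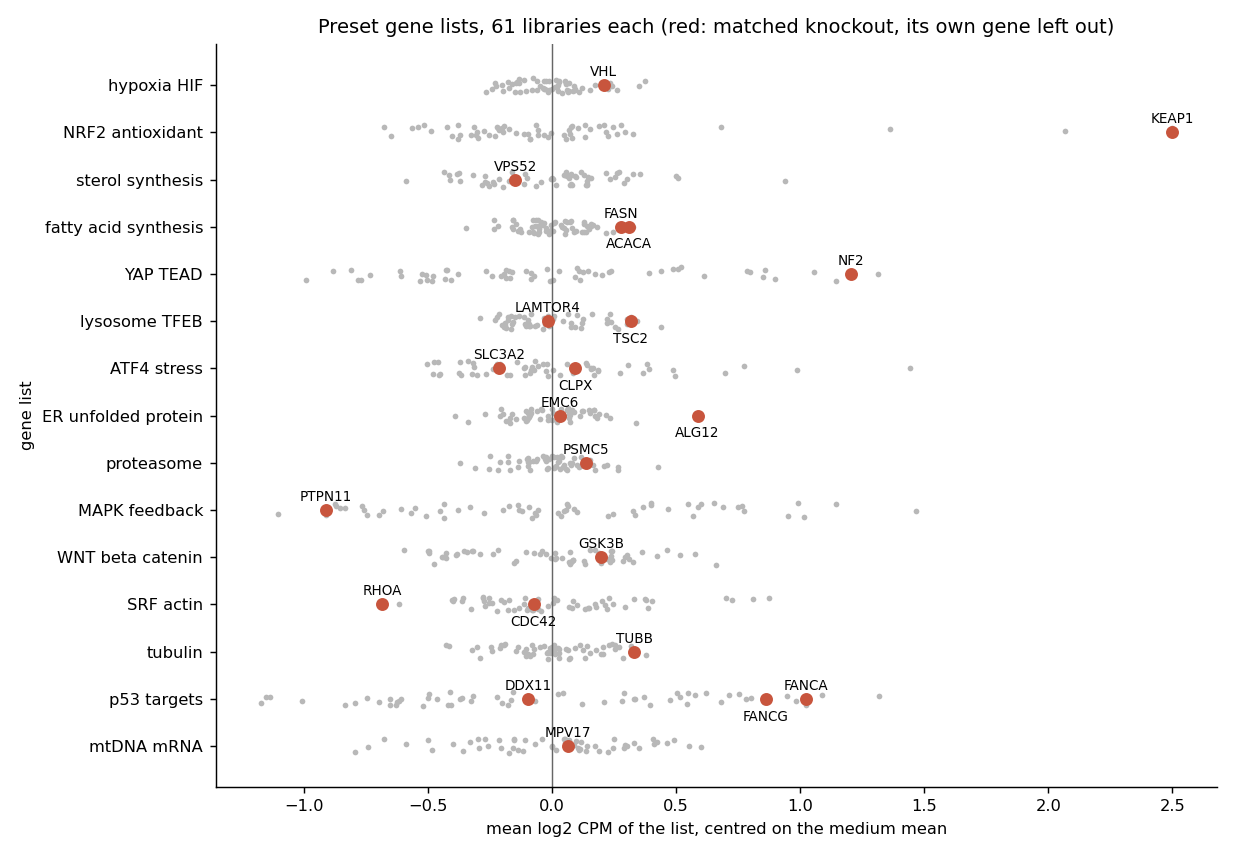
Mean deviation of each preset list from the mean of its medium, in log2 CPM, in all 61 libraries (grey). Red points are the knockouts matched to the list before the data were examined.

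Other genes called in the matched knockouts lay outside their pathways. The RHOA library had higher KLF2 (3.62) and the adhesion molecule L1CAM (2.93), lower ADGRL2 (-3.65) and 0 counts of ZNF595, at least 258-fold lower. VPS52, part of the GARP tethering complex, had higher RGS2 (2.59), NAB2, a corepressor of EGR1 (2.34), and MYADM (1.86), with 0 counts of TRIM32 (at least 380-fold lower) and lower ASTN2 (-6.59), the gene that surrounds it. VHL had higher PCOLCE, a collagen processing enhancer (3.26), and MAPK6 (1.17), and lower ZNF426 (-4.41). FASN had lower EYA4 (-6.60), LIPE, a hormone-sensitive lipase (-6.04), and CTNND1 (-2.21). SLC3A2 had higher COL1A1 (2.64) and lower PIEZO1, a mechanosensitive channel (-1.06). ALG12 had lower PPP2R5D (-3.51) and UAP1 (-3.20). The library labelled PSMC5 had higher RTL9 (4.41) and lower TNFAIP2 (-7.78), and FANCA had higher PRRX1 (6.48) and lower SIM2 (-3.69). MPV17 had higher HOXC4 (5.19) and 0 counts of STX8, at least 119-fold lower. GSK3B had higher MEIS1 (1.70), and LAMTOR4 had higher ABL1 (1.08).

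Knockouts of genes that work together were compared over all tested genes. The kinases GSK3A and GSK3B had the most similar profiles of the 9 preset pairs, with a correlation of 0.607, and each was the closest partner of the other. DLX5, a homeobox gene with a median of 15.2 CPM, had 0 counts in these 2 libraries alone. GSK3A and GSK3B have the nearby library numbers 16 and 19. Pairs that were not preset were as similar, DDX11 and VPS52 (numbers 49 and 50) at 0.624 and ATP5J and NAA38 (53 and 57) at 0.570. The ATP synthase knockouts ATP5J and ATP5L correlated at 0.403, ACACA and FASN at 0.257, COQ7 and COQ9 at 0.1996 and FANCA and FANCG at 0.165. The NatC subunits NAA35 and NAA38 gave 0.028. Of the libraries labelled for complex I, FOXRED1 and NDUFA2 gave -0.008, NDUFA2 and TMEM126A -0.116, and FOXRED1 and TMEM126A -0.470, the lowest of all 1770 pairs. The target transcript was not called lower in NDUFA2 or TMEM126A, and TMEM126A is one of the 5 libraries with the shared profile.

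The mean over the 9 pairs was 0.118 (one-sided permutation p = 0.0380), and permuted labels gave a mean of -0.0187. Simulated unchanged libraries with the same reference gave a correlation of -0.0339 and a covariance of -0.0156, while the covariance was 0.268 for GSK3A and GSK3B and 0.152 for ATP5J and ATP5L. The simulated libraries were drawn independently and share no structure, so they show only what the common reference adds. Pairs that were not preset had covariances as large, 0.291 for DDX11 and VPS52 and 0.202 for ATP5J and NAA38. With separate reference libraries for each member of a pair, the correlations were 0.580 for GSK3A and GSK3B and 0.392 for ATP5J and ATP5L. The p rose above 0.05 with the 2000 most variable genes (0.0528), with the 7 pairs in one medium (0.0905) and without ACACA and FASN (0.0777). Without the 5 correlated libraries, which leaves 7 pairs, the mean was 0.191 (one-sided permutation p = 0.00089). This setting was chosen after the data were seen. It dropped NDUFA2 with TMEM126A (-0.116) and FOXRED1 with TMEM126A (-0.470), the lowest of the 9 pairs. The higher mean and smaller p therefore partly reflect which pairs were removed.

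The wild-type library was set against all knockouts. By edgeR 0 genes were called, and DESeq2 called 2. An unadjusted edgeR p under 0.05 was reached by 363 of 16502 genes. This is a smaller share than the 0.05 that unchanged genes would give. Without the 5 correlated libraries 5 genes were higher in the wild type, by log2 fold changes of 4.64 to 5.61. These were ZNF43, ZNF676, PWWP3B, KIAA1210 and SLITRK4. The folds rest on few reads, since the wild type held 0.163 CPM of ZNF676, 0.228 of PWWP3B, 0.846 of KIAA1210 and 0.0976 of SLITRK4. The other 55 knockouts held 0.236 CPM or less of each. The count filter was set over all 61 libraries, so the 5 libraries that were left out brought these genes past it. ZNF43 and KIAA1210 are among the genes that were on in the 5 libraries, and the wild type held 0.195 CPM of ZNF43 against a mean of 45.1 in the 5.

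Expression was also compared by chromosome, to find shifts that span one. Whether such shifts reflect a change of copy number was not tested. Chromosome 13 was low in the SLX1 library, with a median of -0.88 over 316 genes and 90.8% of them lower, and the same library had a low X chromosome (-0.73) and a high chromosome 8 (0.44). Chromosome 8 was high in DDX11 (0.55) and CDKN2B (0.54) as well. It held 26 of 31 calls in DDX11 and 24 of 34 in CDKN2B, all of them higher. The 3 largest rises in DDX11, FAM86B1 (2.34), MTMR7 (2.15) and SLC7A2 (1.88), lie on that chromosome. TUBB had a low X chromosome (-0.50) and a high chromosome 22 (0.44), and its called genes SMS and YY2 lie on the X and SUN2 and SMTN on 22. POLR2A had a low chromosome 22 (-0.45), and VHL had a low X chromosome (-0.40). The median of X in FANCA was -0.41, from 266 genes between 63343227 and 134428791 with a median of -0.74, while the other 343 genes had -0.03. These 10 shifts of at least 0.4 were not tested, and the SD of a chromosome over the other libraries was 0.058 to 0.15.

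Shifts also covered parts of chromosomes. In WDR73, 46 of 50 called genes lay between 63608618 and 89317261 on chromosome 15, where 240 genes had a median of -0.86. WDR73 itself lies in this segment, and its own log2 fold change was -0.17 (adjusted p = 1). In FANCA, 11 called genes lay at the start of chromosome 18 (158383–13764558, median -0.87), and in KAT7 31 lay on chromosome 10 (274190–70568449, median -0.61). In TMEM94, 13 of 20 lay on chromosome 8 (23385783–43085788, median -0.97). All 5 calls in ACACA, IDS, EOLA1 and TMEM185A among them, lay between 147911951 and 149938811 on the X chromosome. TAPT1 had 0 counts of KIAA1586, ZNF451, BAG2 and RAB23, which are neighbours on chromosome 6. Within 500 kb of a knockout's own target only EFNB3, 190586 bp from POLR2A, fell by 3.24, past the preset limit of -3.

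**Figure D5:**
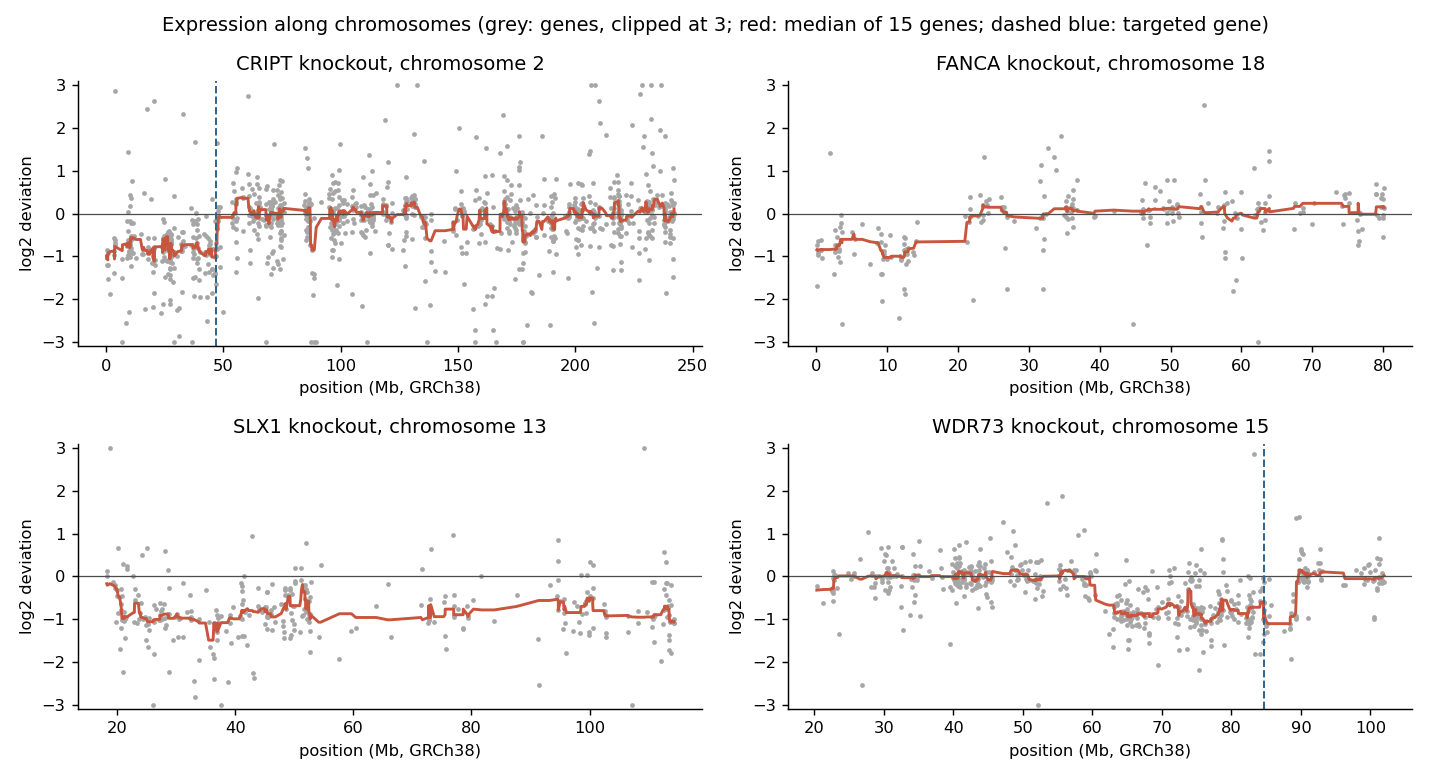
Deviation of each gene from the mean of its medium along 1 chromosome in 4 libraries, CRIPT, FANCA, SLX1 and WDR73, in log2 CPM (clipped at 3). Red is the running median of 15 genes, and the dashed line marks the knockout's own target where it lies on that chromosome.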

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

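The tests without the 5 correlated libraries, with library-number blocks added to that set, of gene absence, of the wild type and of chromosome differences were chosen only after the results were seen. The random regroupings and the chromosome 15 test were written down first, but the margin of 1 SD by which the latter is read here was set after its values were seen. The tests of the 5 and of library-number blocks were changed after the results were seen, from numbers of calls to folds and to the overlap of calls. The test of scaling was changed then too, from library totals to differences between chromosomes.

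A library far from the others of its group stood out in 1 of 27 groups checked. The lysosomal list in the respiration knockouts was at 0.304 in NDUFA2 and between -0.187 and -0.107 in the other 6 (ratio of gap to range 0.836, above the critical value for n = 7). A single group passes this rule by chance about 1 time in 20.

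The number of genes called between media was set against chance, against the profile of the 5 libraries and against library numbers. Of 100 splits of the knockouts into 30 and 30, the real one included, 1 called as many as 951 genes, and the highest other called 656 with 3 of the 5 libraries on one side. Of the other splits 99 called at least 1 gene, and the median of the others was 12. Without the 5, 94 genes were called, below each of the 20 draws without 5 other rich-medium libraries (673 to 1550), but lost calls alone do not show where the changes came from. The 209 falls kept a median of 0.821 of their log2 fold change (quartiles 0.712 and 0.943, none below 0.5), which argues against the profile of the 5 as the main source of the falls. Without 5 others the falls kept 0.964 to 1.068, so the 5 added to the falls too. Each draw without 5 others kept the 5 among fewer rich-medium libraries. It thus raised their weight and is no neutral baseline. Without 5 others the 742 rises kept 1.03 to 1.104, and values above 1 were largely fixed beforehand by that weight. Without the 5 the rises kept a median of 0.583 (quartiles 0.351 and 0.805), so the 5 added to the rises. Their median went from 0.564 (median SE 0.152) to 0.289 (0.137), and 311 were below 0.5 of their fold and 431 were not, so a main share of the 5 and a main share of medium cannot be told apart for the rises as a set. Of 100 splits without the 5, 4 called as many as 94. The others called a median of 14 and at most 881, and 99 of them called at least 1 gene. The remaining calls may thus partly reflect other structure among the libraries. With library-number blocks added the number of calls was 97, but only 39 of the 94 stayed called and 55 did not, although all 94 kept their sign and the median fold ratio was 0.978, so batches along library numbers, which overlap with medium, cannot be told apart from medium here. Each knockout grew in 1 medium only, so which genes were knocked out stays open as an explanation and was not tested. For the respiration comparison the real count was 0, so 100 of 100 splits called as many by necessity and the splits tested nothing. The highest other called 586 and had the 5 libraries split 3 to 2. Several other splits of 3 to 2 called 0 genes, and the source of the 586 was not tested.

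The shared profile of the 5 libraries was set against a mixture of cells, another cell line and a part of the wild-type culture. In all 5 and no other library 13 genes were absent (at most 3 counts), which argues against a mixture of these cells with other HAP1 cells. If the 5 were a line without the extra chromosome 15 fragment of HAP1, the segment that was low in WDR73 should be at -0.4 or lower in each. The medians were -0.203 to -0.0439, against -0.860 in WDR73 and an SD of 0.127 over the other libraries, WDR73 included. All 5 were above -0.4 by more than this SD, which argues against such a line. The segment was still somewhat low in most of the 5. C5orf34 (-0.102), CRIPT (-0.111), POLR2A (-0.122) and TMEM126A (-0.203) lay below CDKN2B (-0.0709), the lowest library outside the 5 apart from WDR73. By the preset band of 0.2 either side of 0 alone the test stayed open, since 1 library narrowly missed it. The wild type was the highest library outside the 5 for 5 of the 8 genes on in the 5, at a median of 1.16% of their level (0.779% after subtraction of the median of the other 55 knockouts from both), which fits a small part of the wild-type culture in the same state as well as carry-over between libraries.

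The chromosome shifts were set against normalization. A scaling factor moves all chromosomes of a library by one amount, so the use of library totals in place of TMM could not test this. In these libraries the median of the other chromosomes was -0.00369 to 0.0279, and each shifted chromosome differed from the others by at least 0.415 (2.76 SD of the other libraries). Shifts were listed at 0.4 or more, and scaling and centring keep most genes near 0, so a difference near this size was largely fixed beforehand. SLX1 and TUBB each had a high and a low chromosome. A single factor per library does not produce opposite shifts, which argues against scaling as the source in these 2 libraries. For the other libraries no conclusion is drawn. The test does not separate a change of copy number from another change that spans a chromosome.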

How the results depend on the processing

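All alternatives without the 5 correlated libraries, or without libraries with chromosome shifts, and the lists without 1 respiration knockout were chosen only after the results were seen. No paired analysis was possible because each knockout had 1 library and the 2 media held different knockouts. Of 768 values of genes by medium under alternatives, 517 kept their direction and side of the threshold, 29.4% were weaker, 11 stronger and 14 reversed. Of 1072 values of genes in a knockout, 982 kept both, 79 were weaker, 5 stronger and 6 reversed. Of the matched list values all but 2 kept direction, as did all but 2 pair values, and all 20 list values by medium and 22 by respiration did. Of 20 chromosome values 19 stayed.

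Genes called by medium (951) numbered 1780 without the count filter, where 38569 genes were tested, 421 with library-number blocks, 0 in libraries 1 to 20, where 15 libraries remained, 596 without respiration knockouts and 547 without libraries with chromosome shifts. Library totals without TMM gave 928. Without the 5 libraries they numbered 94, with blocks added 97, with DESeq2 104 and without GSK3B too 105. The respiration comparison (0) gave 4 with DESeq2, 3 in rich medium, 2 with other mitochondrial knockouts added, 3 without the filter, 2 without the 5, 1 without libraries with chromosome shifts, and 0 to 15 when 1 knockout was left out (15 without TMEM126A, 4 without COQ7). The 3140 calls of the knockout outlier test rose to 8807 against libraries outside the 5. Each of the 5 was kept there and tested without the others of the 5, and they held most of these calls. Without the fold threshold there were 4915 calls. In knockouts with a matched list DESeq2 made 1043 calls where edgeR made 244. For the wild type (0) DESeq2 gave 2 and leaving out the 5 gave 5. The difference in calls of chromatin knockouts (66) was 18.5 without BRD4, 55 with blocks, 85.5 without the fold threshold and 101.5 without the 5. Targets lowest in their own library (36) numbered 34 with unstranded counts, 38 with library totals and 39 within the same medium. The mean pair correlation was 0.124 with 2000 variable genes, 0.100 in one medium and 0.101 without ACACA and FASN. Within 2 Mb of POLR2A 2 genes passed the limit of -3, EFNB3 and WSCD1, and WSCD1 was at 0 in all 5 correlated libraries. Shifted chromosomes (10) numbered 11 with a mean count of at least 100.

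Directions reversed as follows. Without the 5, KIAA1210 was at -0.15, ACTL8 at -0.228 and TEX19 at -0.32. With blocks added these were -0.25, -0.0787 and -0.53, and with DESeq2 KIAA1210 was -0.19 and ACTL8 -0.23. Without the 5 and GSK3B the 3 were at -0.0974, -0.233 and -0.301, in the order KIAA1210, ACTL8 and TEX19. In libraries 1 to 20 HES1 was at 1.52, SERTAD1 at 0.018 and IER5 at 0.093. DEPP1 in respiration knockouts was at -0.15 without NDUFA2 and at up to 2.46 (without ATP5J) without any other. SRF and actin genes in CDC42 were at 0.0674 as a median and 0.115 at unit SD. The Spearman correlation of FOXRED1 and NDUFA2 was 0.0850, and NAA35 and NAA38 were at -0.138 without the 5. Target transcripts near 0 turned as well. CDKN2B was at 0.054 with unstranded counts and 0.041 without the 5, PIGO at -0.034 with blocks and -0.030 with totals, and PTAR1 at 0.0056 with a mean count of at least 50 and 0.086 with blocks. The cause was not tested, except where fewer libraries or more genes were tested as stated. One library per knockout and the spread among the other 60 limit small changes, of which the simulated single-library test found 16% at 2-fold.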

Other observations

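The observations here were all chosen only after the values were seen. Apart from the calls of single genes, none was tested. Several knockouts stood at the edge of preset lists that had not been matched to them. NDUFA2 had the highest mean for ATF4 stress targets (1.44) and sterol synthesis (0.94) and the lowest for MAP kinase targets (-1.10) and the G2/M cell cycle (-0.33). ACACA was the second highest for ATF4 targets (0.99) and the highest for serine and one-carbon genes (0.53). SLC3A2, the heavy chain of amino acid transporters and a partner of integrins, was highest for MAP kinase targets (1.47), SRF and actin genes (0.87), fibroblast markers (2.36) and the proteasome (0.43). ATP5J was lowest for mitochondrial transcripts (-0.79), sterol synthesis (-0.59) and fatty acid synthesis (-0.35), and CLPX was highest for mitochondrial transcripts (0.60). The library labelled PSMC5 was highest for p53 targets (1.32), and HDAC3 for nuclear RNAs (0.95).

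The library labelled TAZ was the second highest for NRF2 targets (2.07) after the library labelled KEAP1, and the highest for YAP and TEAD targets (1.32) and selenoproteins (0.37). TXNRD1 (1662 CPM against 431) and G6PD (593 CPM against 130), 2 NRF2 targets, were among its called genes, with log2 fold changes of 1.95 and 2.19. The label does not say whether TAZ means TAFAZZIN or WWTR1. RHOA was lowest for YAP and TEAD targets (-0.99).

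ATAD1 (chromosome 10: 87751512–87841343) and its neighbour PTEN (87863113–87971930), a phosphatase that opposes PI3 kinase, were at 0.316 CPM or less in 7 libraries, ATP5L, EXO1, FASN, PGLS, PSMC5, PTPN11 and WDR73. In the other 54 libraries ATAD1 was at 33.6 CPM or more and PTEN at 37.5 CPM or more. PAPSS2, the next gene on one side, was at 1.38 to 3.21 CPM in the 7 and at 4.24 CPM or more elsewhere, while MINPP1 beyond it was in the range of the others. None of the 7 labels names a gene of this region.

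Of 10952 genes with a median of at least 5 CPM, 162 were absent (at most 3 counts) from 1 to 5 libraries. These were 59 genes absent from 1 library, 35 from 2 and 68 from 3 to 5, and 48 libraries lacked at least 1. GPR27 had 0 counts in CDC42 and in the library labelled KEAP1. The profiles of DDX11 and VPS52 correlated at 0.624, ATP5J and NAA38 at 0.570 and BCL2 and EMC6 at 0.538, near the 0.607 of GSK3A and GSK3B. DDX11 and VPS52 have the library numbers 49 and 50. Among 119 flanks of up to 30 genes beside a target (the smallest held 10), 4 had a median of -0.4 or lower. These were the lower side of CRIPT (-0.92, SD 0.0799 over the other libraries), both sides of WDR73 (-0.65 and -0.88, SD 0.157 and 0.0628) and the higher side of NDUFA2 (-0.86), where the other libraries varied more (SD 0.559). In C5orf34, 65 called genes between 93561786 and 248849517 on chromosome 1 were higher, with a median of 0.67 over the segment. The largest absolute median of another library over this segment was 0.58. Chromosome 1 also held 85 higher calls in TMEM126A and 50 in POLR2A, which share the profile of the 5 libraries with C5orf34.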
